A study of Homo sapiens with 21 samples.

How the data were processed

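Surface antigens were measured on MOLM-13 cells, an established human acute myeloid leukemia line, that had been cultured in medium with a compound. Per the labels' protocols, the cells were stained with Total-Seq B antibodies, each of which carries a DNA barcode, and the barcodes were amplified straight from the stained cells by PCR and sequenced. A value is therefore a number of barcode reads for 1 antibody in 1 well, and it depends on the antibody bound, on the number of cells and on amplification. Each library is a pool of the wells of 1 replicate. Assay 1 has 5 libraries, and Assay 2 has 16, which are 4 libraries of each of 4 plates. The study states 85 compounds for Assay 1 and 1101 for Assay 2; 83 names stand in the table of Assay 1 and 1101 in that of Assay 2. Doses, treatment times and the number of cells per well are not given in the sources used here, so no dose enters any comparison.

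The authors deposited 1 table of raw read counts per assay, with antibodies down and wells across, and all values used were whole-number counts. Per the submitters' processing notes, the reads were handled with cutadapt, STAR and UMI-tools, for which versions, settings and a reference are not given. Whether reads with the same molecular identifier were collapsed is not stated either, so the counts may hold copies of 1 molecule, and the spread between wells, not counting error, was used for every test. Wells were assigned to samples from the replicate, plate and library names in the table headers. In all, 116 columns were not used: 96 carry the number of a replicate 6 for which no sample is described, and 20 carry no compound name. A SpikeIn line, which names no antigen, was kept out of the well totals; it held 0.374% of the Assay 1 counts and 0.0079% of the Assay 2 counts.

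Wells named C (Assay 1, 59 wells) or CTRL (plate 4 of Assay 2, 56 wells) were taken as control wells; what they received is not given. Plates 1, 2 and 3 of Assay 2 have 0 control wells in the table, and there each compound was set against all other compound wells of its libraries. The test, the blocks, the control choice, the antibody and compound groups and most alternatives were fixed before the data were examined; tests added later are named at the top of each closing part. In the Assay 2 table the libraries of a plate carry the marks R1 and R2. They are called first-round and second-round libraries here, since their link to a culture day is only a reading of the numbering; the sample titles put replicates 1 and 2 under day 1 and replicates 3 and 4 under day 2. Whether wells of 1 compound came from separate cultures is not stated, so all p-values measure only the spread between the wells of these samples. The fit treats the 4 libraries of a plate as independent, although they agree more within a round than between rounds.

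For each compound and antibody, the compound's wells were compared with the control wells of the same libraries in edgeR (4.0.16, R 4.3.3) with the quasi-likelihood F test, a negative binomial dispersion per antibody, TMM factors across the wells of a plate and the library as a block. Wells with fewer than 100 counts were left out (1 well). The Benjamini-Hochberg adjustment ran over all pairs of an assay at a threshold of 0.05, and a pair past it is called changed. Log2 changes are relative to the other antibodies of the same well, so a factor shared by all antibodies of a well is divided out; any further dependence of relative levels on the well total was not modelled. Standard errors (SE) come from the F statistic of the fit. On plates 1, 2 and 3 of Assay 2 a fit held up to 4 wells of the compound and up to 1276 others. The SE there reflects mainly the spread among the other wells and can lie far below that between the compound's own libraries. Log2 changes per library, for the spread, are differences of log2 levels (0.5 added) from the median control well of that library. A pair was said to go the same way when all its libraries had the same sign, which holds by design for treatments with wells in 1 library.

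Well totals were compared with an exact permutation test within libraries (two-sided, on log2 totals with 1 added), and classes with an exact Wilcoxon rank-sum test (two-sided) of the members' log2 changes against those of all other compounds. Classes were matched by name and needed at least 3 members; 14 of those listed beforehand had them in Assay 2. Related compounds on 1 plate were compared in a single edgeR fit and those on different plates by the normal distribution from their SEs, with 95% intervals. The difference between rounds was an interaction term in the edgeR fit. Agreement between libraries is Pearson's r across compound-antibody pairs, which are not independent replicates. Further tools were limma (3.58.1), DESeq2 (1.42.0), Python (3.11.15), numpy (2.4.6), scipy (1.17.1), pandas (2.3.3) and matplotlib (3.10.9).

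The column order of the libraries was the same on plates 1, 2 and 3, so each compound there has a column place, and wells at that place on the other plates held other compounds. In a test added after the data had been seen, each compound was compared with the wells at its own place in the libraries of the other plates, each antibody being first scaled to its library's median well. The reference was thus 1 treated compound on each other plate, and all its wells entered as independent, without a library term. A call can therefore also be lost because those compounds act like the one tested. Plate 4 has no partner for this comparison. In Assay 1 matching by place was possible only for PFI90, IFNG and TNFa, against control wells.

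The compound-antibody pairs named were chosen by a rule. For each antibody these are the largest rise and the largest fall among changed pairs that went the same way in every library and whose mean well total was at least 25% of the control. The 5 compounds with the most changed antibodies (with ties), up to 4 members of a class past the class test, the related compounds, the 5 lowest and 3 highest totals past the threshold, IgG and the levels in control wells complete it. Pairs outside the rule appear as examples in the parts on column place, on rounds and on PFI90, IFNG and TNFa, and all changed HDAC inhibitors are named. Other pairs outside the rule are said to be so. The antibody groups were myeloid differentiation (CD11b, CD14, CD86), AML antigens and progenitor markers (CD33, CD123, CD38, CD70, CLL1, Flt3), checkpoint and phagocytosis signals (CD47, CD86), antigen presentation (HLA_ABC, HLA_E), pan-leukocyte (CD45) and isotype control (IgG); CSF1R, AnnexinV, Fas and TNFRSF1B belong to no group. Of 18 antibody names, 14 matched 1 human gene symbol or synonym, CLL1 matched 2 genes and AnnexinV, HLA_ABC and IgG matched none, so the names are printed as deposited.

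The procedure was tested on simulated counts with the real means, library sizes and layout. In Assay 1, with 12 or 13 simulated pairs per fold, it recovered 53.8% of pairs changed 1.1-fold and 100% of those changed 1.25-fold or more, and called 3 of 1195 unchanged pairs. In Assay 2 it recovered 14% of pairs changed 1.1-fold, 96% at 1.25-fold and 100% at 1.5-fold and above, and called 7 of 18517 unchanged pairs. The simulation holds no effect of a well's position and no single aberrant wells, so its share of false calls is not that of the real wells. It also gave all antibodies of a library 1 common dispersion. Real control wells of Assay 1 had log2 SDs from 0.028 for CD123 to 0.082 for CD11b. The recovered shares are therefore not those of each antibody. Alternatives covered the scaling (DESeq2 size factors, the total count, IgG, CD45 or SpikeIn as the denominator), the test (DESeq2's Wald test, limma-voom), minimum well totals, the block, the control wells, a fold threshold of 1.5 and leaving out each library in turn. To ask whether chance gives as many changed pairs, compound names were drawn at random among the wells within each library (99 draws in Assay 1, 24 in Assay 2).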

Results

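The data are barcode counts of surface antigens on MOLM-13 cells, an acute myeloid leukemia (AML) line that carries a KMT2A fusion and an internal tandem duplication in FLT3. Each well held cells cultured with 1 compound, and each antibody's barcode was counted per well. Assay 1 has 5 libraries with 480 wells, 83 named compounds or cytokines and 15 antibodies. Assay 2 has 16 libraries with 4460 wells, 1101 compounds and 17 antibodies, in 4 libraries for each of 4 plates. The Assay 1 libraries held 3244253 to 4180137 counts and the Assay 2 libraries 7554540 to 9569188. The median well held 39176 counts in Assay 1 and 25649.5 in Assay 2, where single wells ran from 91 to 379692.

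AnnexinV, a phosphatidylserine-binding protein used to mark dying cells, took the largest share of control-well counts in both assays: 12.3% ± 0.0522 (SD, n = 5 libraries) in Assay 1 and 23.5% ± 1.72 (SD, n = 4) on plate 4 of Assay 2. The M-CSF receptor CSF1R held 9.25% ± 0.487 and the costimulatory ligand CD86 8.72% ± 0.184 in Assay 1. The integrin CD11b and the lipopolysaccharide co-receptor CD14, both monocyte markers, were low there at 3.01% ± 0.152 and 3.45% ± 0.168. The isotype control IgG, which measures unspecific binding, held 9.34% ± 0.337 in Assay 1 and 4.32% ± 1.39 in Assay 2. In Assay 1 every antibody other than AnnexinV thus lay below the isotype control in relative counts, with CSF1R the closest to it. In Assay 2 antigens such as CD11b and CD38 (2.60% ± 0.164) lay below it. Antibodies carry no common scale. Log2 changes correlated between libraries with a median Pearson's r of 0.312 in Assay 1 (10 library pairs, 0.161 to 0.575) and 0.187 in Assay 2 (24 pairs), across compound-antibody pairs that are not independent. In Assay 2 it was 0.226 to 0.459 between libraries of the same round and 0.0893 to 0.202 between rounds.

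Assay 1 asked which of 83 compounds shift surface antigens relative to control wells. Shifts were small: 116 of 1245 compound-antibody pairs changed, 76 up and 40 down, with a median size of 0.10 on the log2 scale, and they belonged to 51 compounds. CD14 rose with 16 compounds, AnnexinV with 13 and CSF1R with 12, and none of these 3 fell with any compound, although AnnexinV fell with 2 under total-count scaling and CSF1R with 1 when IgG was the denominator. The leukocyte phosphatase CD45 fell with 8 compounds and rose with 2. The NAD-consuming enzyme CD38 fell with 7 and rose with 1, which became 1 and 1 with IgG as the denominator and turned to 1 fall and 2 rises with CD45 as the denominator or against all other compound wells. The phagocytosis checkpoint CD47 rose with 6 and fell with 0, and rose with 2 and fell with 3 against all other compound wells. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 105 of the 116 pairs went the same way in every library. For 11 of these, the pairs of PFI90, IFNG and TNFa, this holds by design, because they have wells in 1 library only. All 83 compounds share the same control wells, so their signs are not independent: CD14 was positive for 70 compounds against a range of 2 to 66 over 99 random assignments of names, with at most 4 rises in any of them. AnnexinV was positive for 61 against a range of 19 to 66, with at most 2 rises. Control wells of Assay 1 stand at fixed column places, which random names do not keep, so an effect of place on these counts is not excluded. Against all other compound wells in place of the control wells, 72 pairs changed, 40 up and 32 down. CD14 then rose with 2 compounds, CSF1R with 2, and CD45 rose with 4 and fell with 4.

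By antigen group, myeloid differentiation markers changed in 32 of 249 pairs, 27 up and 5 down (36 when adjusted over the list alone). The largest rises of CD14 and CD86 that held one direction over 5 libraries were those with the antipsychotic ARIPIPRAZOLE (0.27) and with DECAMETHONIUM_BROMIDE (0.20; 0.07 without replicate 4). AML antigens and progenitor markers changed in 27 of 415 pairs, 9 up and 18 down (20 adjusted over the list alone), a balance that turned to 14 up and 8 down with IgG as the denominator, 20 and 10 with CD45 as the denominator, and 14 and 7 against all other compound wells. The checkpoint and phagocytosis signals CD47 and CD86 changed in 20 of 166 pairs, 15 up and 5 down (23 over the list alone), against 7 and 7 when the reference was all other compound wells. Antigen presentation molecules changed in 10 of 166, 6 up and 4 down (4 over the list alone), against 3 up and 11 down with total-count scaling, 5 and 10 when every well entered a single fit and 3 and 8 against all other compound wells. CD45, alone in its group, changed in 10 of 83 pairs (11 adjusted over the list alone). IgG rose with 1 compound and fell with 5 (6 pairs over the list alone), but rose with 3 and fell with 2 when CD45 was the denominator and rose with 2 and fell with 1 against all other compound wells. The share of rises was 65.5% as tested, 45.7% with total-count scaling, 86.0% with IgG and 81.2% with CD45 as the denominator, 55.6% against all other compound wells and 46.0% when every well entered a single fit. With SpikeIn as the denominator 1 pair rose and 12 fell, and 3 of these 13 were among the 116.

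AZACITIDINE, a DNA-hypomethylating cytidine analog used in AML, raised AnnexinV by 0.12 (SE 0.019, n = 5 libraries, edgeR's adjusted p = 2.7e-08), the sialic-acid-binding receptor CD33 by 0.09 (SE 0.022), CD45 by 0.14 (SE 0.036) and CD38 by 0.09 (SE 0.026). CD33 (−0.04) and CD38 (−0.05) turned negative with CD45 as the denominator, as did CD45 (−0.58), CD33 (−0.62) and CD38 (−0.63) with SpikeIn. The rise of AnnexinV was smaller than that of CD45 too, and smaller than that of the ratio of SpikeIn to antibody counts (0.76). The proton pump inhibitor RABEPRAZOLE_SODIUM raised CD47 by 0.14 (SE 0.030, adjusted p = 0.000544) and lowered CD45 (−0.18, SE 0.038). CLAVULANATE_LITHIUM, a salt of the beta-lactamase inhibitor, raised AnnexinV by 0.14 (SE 0.018, adjusted p = 8e-11). ARIPIPRAZOLE raised CD14 by 0.27 (SE 0.045) and lowered CD38 (−0.11, SE 0.026), with a single library at 0.75 and the others at 0.06 to 0.19 for CD14. The glucocorticoid ISOFLUPREDONE_ACETATE lowered CD86 (−0.15, SE 0.030), SODIUM_PHENYLBUTYRATE lowered CD70 (−0.10, SE 0.021), EUCALYPTOL lowered IgG (−0.11, SE 0.028), and the cardiac glycoside PROSCILLARIDIN raised the class I molecules read as HLA_ABC by 0.08 (SE 0.021). With SpikeIn as the denominator the direction also turned for RABEPRAZOLE_SODIUM with CD47 (−0.03), CLAVULANATE_LITHIUM with AnnexinV (−0.34), SODIUM_PHENYLBUTYRATE with CD70 (0.02) and EUCALYPTOL with IgG (0.04), and with CD45 for ARIPIPRAZOLE with CD38 (0.03). Among the pairs listed next, CD45 turned that of VINPOCETINE with HLA_ABC, SpikeIn that of DROSPIRENONE with IgG, and both that of CLAVULANATE_LITHIUM with HLA_E. Only PFI90, IFNG and TNFa could be matched by column place in Assay 1, so place is not excluded for the other pairs. Of the 21 pairs named by rule, 9 lost the call without at least 1 library. These were AZACITIDINE with CD45 (0.12 without replicate 2) and CD38 (0.07 without replicate 5), VINPOCETINE with HLA_ABC (−0.07, SE 0.022; −0.06 without replicate 1, and −0.07 without 2, 3 or 5), CLAVULANATE_LITHIUM with HLA_E (0.07, SE 0.020; 0.03 without replicate 1, 0.07 without 2 or 3) and TRAVOPROST with CD70 (0.09, SE 0.022; 0.07 without replicate 3). The others were the progestin DROSPIRENONE with IgG (0.10, SE 0.028; 0.08 without replicate 1 or 4), PFI90 with CSF1R (0.14 throughout, lost through the adjustment without 2, 3 or 4), DECAMETHONIUM_BROMIDE with CD86 (0.20, SE 0.040; 0.07 without replicate 4) and ACETOPHENAZINE_MALEATE with the lectin CLL1 (−0.12, SE 0.032; −0.11 without replicate 3).

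The compounds that changed the most antigens were RABEPRAZOLE_SODIUM and the prostaglandin analog TRAVOPROST, with 6 each. Beyond CD47 and CD45, the calls of RABEPRAZOLE_SODIUM were CD70 (0.08; 0.07 without replicate 2, 0.05 without 3), CSF1R (0.13; 0.10 without 3), CD14 (0.11; 0.04 without 5, also lost without 2 at 0.12 and 3 at 0.11) and CLL1 (−0.11; −0.09 without 3, −0.10 without 4 or 5). Control wells at the column places of PFI90 differed from other control wells by 0.07 for CD47, −0.07 for CD45 and 0.09 for CSF1R. For CD70 the difference was 0.07, for CLL1 −0.08 and for CD14 −0.0003. RABEPRAZOLE_SODIUM and VINPOCETINE could not be matched by place, so their calls cannot be told apart from an effect of place. TRAVOPROST raised CSF1R (0.13; 0.12 without replicate 2, 0.10 without 4), CD86 (0.12; 0.08 without 1, 0.11 without 3) and CD14 (0.11; 0.10 without 3), and lowered IgG (−0.09; −0.09 without 2, −0.08 without 3) and CD38 (−0.08; −0.05 without 3, also lost without 1, 2 or 5). AZACITIDINE and VINPOCETINE changed 5 antigens each, and 7 further treatments changed 4, among them TNFa and the lysine demethylase inhibitor PFI90. All 5 calls of VINPOCETINE and 3 of AZACITIDINE were lost without at least 1 library. So were all 4 each of AMMONIUM_LACTATE, ONDANSETRON and DECAMETHONIUM_BROMIDE. MYCOPHENOLATE_MOFETIL lost 3 of 4, CLAVULANATE_LITHIUM 2, PFI90 1 and TNFa 0. PFI90 and TNFa have wells in 1 library only, so leaving out another library changes the adjustment but not their values. Their counts therefore say nothing of agreement between libraries. A fold change of 1.5 was passed by 2 pairs, both outside the naming rule because their libraries differed in sign, and named here after their values were seen: CSF1R with CINTRIAMIDE (0.78, SE 0.11, libraries from −0.03 to 2.21; 0.08 without replicate 5, where the call was lost) and CD14 with ZOMEPIRAC_SODIUM (0.68, SE 0.078, libraries from −0.19 to 1.34). The largest rise of CD11b was that with PFI90 (0.19, SE 0.043; 1 library, not past the threshold when matched by column place). Also named after their values were seen are the calls for CD11b with MYCOPHENOLATE_MOFETIL (0.15; lost without replicates 1, 2, 3 or 5, at 0.13 to 0.16), and for the IL-3 receptor CD123, with CARBADOX (−0.06; −0.05 without replicate 3, 4 or 5). Without replicate 3, 44 pairs changed in the whole assay, and without replicate 2, 57.

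**Figure D1:**
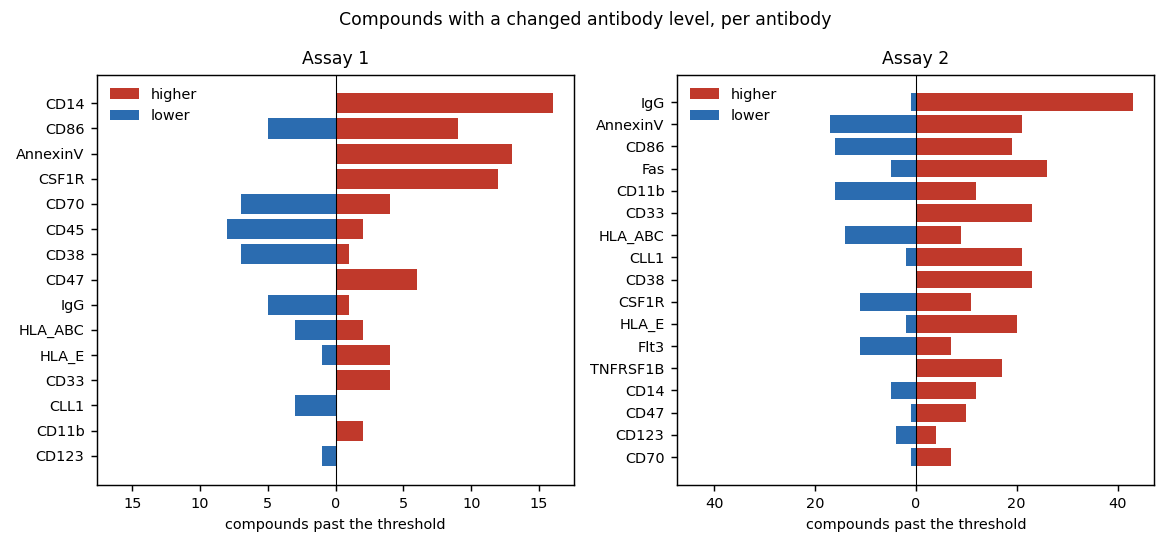
Number of compounds with a changed level per antibody in Assay 1 (83 compounds) and Assay 2 (1101 compounds), with rises in red and falls in blue on an axis of counts. CD14 (16 rises) leads in Assay 1, and IgG (43 rises, 1 fall) in Assay 2.

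PFI90, interferon gamma (IFNG) and TNFa stand apart from the other treatments in layout, with 7 wells each in 1 library. TNFa raised CSF1R by 0.11 (SE 0.021), CD47 by 0.08 (SE 0.024) and CD70 by 0.06 (SE 0.019) and lowered CD45 (−0.11, SE 0.025); IFNG raised CSF1R by 0.10 (SE 0.025) and AnnexinV by 0.04 (SE 0.014) and lowered CD45 (−0.10, SE 0.036). IFNG, which induces class I molecules in many cell types, gave −0.04 (SE 0.022) for HLA_ABC and −0.02 (SE 0.023) for HLA_E, neither past the threshold. PFI90 raised CD86 by 0.14 (SE 0.027) and lowered HLA_E (−0.09, SE 0.024). Of the 11 calls of these 3 treatments, edgeR kept 0 when the wells were matched to control wells at the same column place, where the median change went from 0.10 (SE 0.025) to 0.037 (SE 0.041). At an unadjusted p under 0.05, 2 of the 45 matched values remained.

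Well totals, which rise and fall with the number of cells and with amplification, changed for 0 of 83 compounds in Assay 1 by the exact permutation test after adjustment, and for 13 at an unadjusted p under 0.05. The lowest p values belonged to TNFa (−0.36 in 7 wells, exact permutation p = 0.000612, adjusted p = 0.0508, two-sided), IFNG (−0.32, p = 0.00341, adjusted p = 0.124) and VINPOCETINE (−0.36, from −0.51 to −0.21 in 5 libraries, exact p = 0.00517, adjusted p = 0.124). limma called 1 compound, TNFa, the permutation test without replicate 5 called 7, and setting each compound against all other compound wells called 15, of which 5 were higher and 10 lower.

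Assay 2 asked the same of 1101 compounds. Of 18717 pairs, 391 changed, 285 up and 106 down, in 232 compounds, and the median size was 0.17. IgG rose with 43 compounds and fell with 1. The death receptor Fas rose with 26 and fell with 5, and CD33, CD38 and the TNF receptor TNFRSF1B rose with 23, 23 and 17 and fell with 0, but with IgG as the denominator CD33 rose with 30 and fell with 6, CD38 rose with 20 and fell with 15, and TNFRSF1B turned to 15 rises and 18 falls. CD11b rose with 12 and fell with 16, and HLA_ABC rose with 9 and fell with 14. The test was again edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 298 pairs went the same way in all 4 libraries. Rises made up 72.9% of calls as tested, 63.1% with total-count scaling and 37.4% with IgG as the denominator (222 up and 372 down). The 141 compounds of plate 4 share control wells. In the separate fit used for random names, with 1 dispersion per plate and antibody and thus other counts than above, IgG was positive for 92 of them and rose with 18, against 8 to 106 positive and at most 1 rise over 24 random assignments of names; in that fit Fas was positive for 93 and rose with 10, against 34 to 115 and at most 3. Against all other compound wells, IgG rose with 17 compounds and fell with 1.

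Of the antigen groups, AML antigens and progenitor markers changed in 103 of 6606 pairs, 85 up and 18 down (87 adjusted over the list alone), which became 85 up and 130 down with IgG as the denominator. Among pairs that went the same way in every library, the largest rise of CD38 was that with GSK620 (0.32; 0.07 against wells at its column place) and the largest of CD33 that with KDM4D_IN_1 (0.38; 0.18 without replicate 4). Myeloid differentiation markers changed in 80 of 3303 pairs, 43 up and 37 down (83 over the list alone), against 38 up and 53 down with total-count scaling and 40 up and 93 down with IgG. Among the 52 that held one direction, 16 rose and 36 fell. Antigen presentation molecules changed in 45 of 2202 pairs, 29 up and 16 down (43 over the list alone), against 28 and 28 with total-count scaling and 23 up and 57 down with IgG. The checkpoint and phagocytosis signals changed in 46 of 2202 pairs, 29 up and 17 down (48 over the list alone), against 27 up and 33 down with total-count scaling and 32 up and 51 down with IgG. IgG itself changed in 44 of 1101 pairs (62 over the list alone).

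SGI_1027, a DNA methyltransferase inhibitor, changed 11 of 17 antigens, more than any other compound. It lowered CD11b (−0.73, SE 0.087, n = 4 libraries), CD86 (−0.53, SE 0.057), CD14 (−0.40, SE 0.069), HLA_ABC (−0.33, SE 0.033), CLL1 (−0.25, SE 0.054) and CSF1R (−0.18, SE 0.049). It raised AnnexinV by 0.53 (SE 0.041), IgG by 0.35 (SE 0.037), Fas by 0.23 (SE 0.040), the receptor tyrosine kinase Flt3 by 0.17 (SE 0.032) and CD123 by 0.15 (SE 0.029), of which Flt3 (−0.19) and CD123 (−0.21) turned negative with IgG as the denominator, and the rise of Fas was smaller than that of IgG too. Its wells held 60.0% of the reference count. Set against wells at the same column place on other plates, 9 of the 11 stayed past the threshold, with CD11b at −0.57 (SE 0.054), CD86 at −0.48 (SE 0.040) and AnnexinV at 0.38 (SE 0.080), while Fas (0.12) and CSF1R (−0.11) did not. Leaving out replicate 3 ended the call for CLL1 (−0.21), and leaving out 1 (−0.18), 2 (−0.17) or 4 (−0.16) that for CSF1R.

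**Figure D2:**
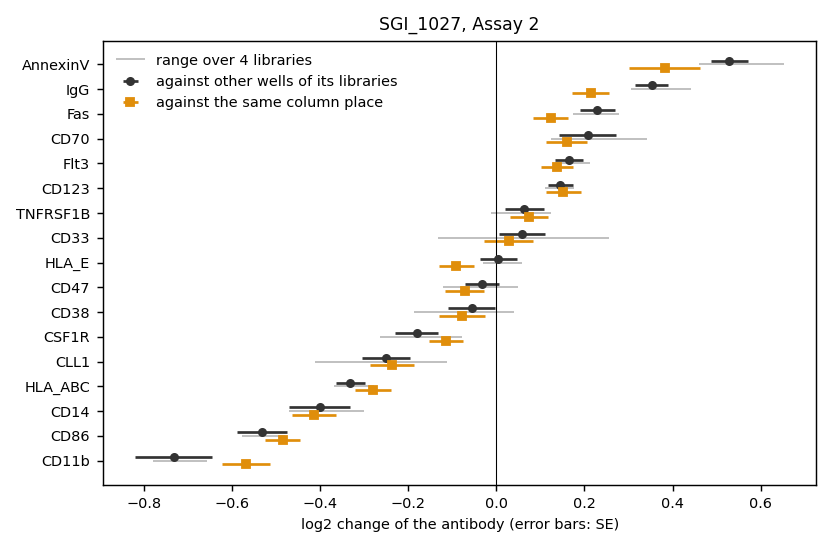
Log2 change of each of the 17 antibodies with SGI_1027 against the other wells of its libraries (black, error bars SE, grey range over 4 libraries) and against wells at the same column place on other plates (orange squares). CD11b lay lowest at −0.73 and −0.57, and AnnexinV highest at 0.53 and 0.38.

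On plate 4, which has control wells, Seclidemstat, an inhibitor of the demethylase LSD1, changed 9 antigens at a well total of 95.1% of control: Fas rose by 0.27 (SE 0.025) and CD38 by 0.21 (SE 0.042), while CD86 (−0.32, SE 0.037) and CD11b (−0.24, SE 0.047) fell. The SYK and JAK inhibitor Cerdulatinib_(hydrochloride) changed 8, with CD11b at −0.49 (SE 0.059), AnnexinV at 0.39 (SE 0.046), Fas at 0.39 (SE 0.030) and CD86 at −0.26 (SE 0.042), in wells that held 34.0% of the control count. MAT2A_inhibitor_1, named for the enzyme that makes S-adenosylmethionine, changed 8 in wells at 333% of control; CLL1 rose by 0.19 (SE 0.028) and CD38 by 0.20 (SE 0.038), and CSF1R (−0.20, SE 0.044), CD86 (−0.19, SE 0.034) and AnnexinV (−0.19, SE 0.046) fell. Nampt_IN_3, named for the NAD salvage enzyme, changed 8, led by CD11b (−0.36, SE 0.046), IgG (0.25, SE 0.030) and Fas (0.15, SE 0.026). Its rises of Fas and AnnexinV were smaller than that of IgG. On plate 3, the BET inhibitor GSK620 changed 8, among them CD11b (−0.42, SE 0.077) and AnnexinV (0.36, SE 0.047), in wells at 32.1% of the reference, and 0 of these stayed past edgeR's threshold against wells at the same column place. Several smaller calls were lost when 1 library was left out, most of them with little change in size. For Seclidemstat this was AnnexinV (0.18; 0.17 without replicate 3, 0.14 without 4), and for Cerdulatinib_(hydrochloride) CSF1R (−0.20; −0.14 without 2, −0.21 without 4) and CD38 (0.18; 0.16 to 0.19 without 1, 2 or 4). For MAT2A_inhibitor_1 they were CD70 (0.36; −0.02 without 4), CD33 (0.22; 0.29 without 2, 0.15 without 3, 0.16 without 4) and Flt3 (−0.11; −0.08 without 2, −0.09 without 4). GSK620 lost 4 calls: CSF1R (−0.18; −0.20 without 1, −0.12 without 2, −0.19 without 4), CD33 (0.23; 0.19 without 1, 0.22 without 2), HLA_E (0.21; 0.19 without 1, 0.18 without 4) and HLA_ABC (−0.14; −0.12 without 1, −0.14 without 2). Nampt_IN_3 lost 5: AnnexinV (0.16; 0.15 without 3, 0.14 without 4), CSF1R (−0.17; −0.16 without 2, −0.17 without 3), CD86 (−0.16; −0.14 without 1, −0.13 without 2), CLL1 (−0.13; −0.15 without 1, −0.11 without 3 or 4) and CD14 (−0.13; −0.07 without 1, −0.11 without 2, −0.12 without 4, and −0.21 with the call kept without 3).

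Largest rises and falls of the remaining antibodies included Fas with Dot1L_IN_4 (0.42, SE 0.045; 0.11 against wells at its column place, wells at 33.3% of the reference) and CLL1 with ACY_1083 (0.20, SE 0.042; 0.09 at its column place). Several of the largest rises shrank when 1 library was left out. HLA_E with NV03 was 1.75 (SE 0.053, but SD 1.66 over 4 libraries) and 0.08 without replicate 1. CD86 with T_3775440_hydrochloride was 0.68 (SE 0.088, but SD 0.82 over 4 libraries) and 0.06 without 4. CD11b with the PARP inhibitor Simmiparib was 0.41 (SE 0.071) and 0.12 without 2. CD33 with KDM4D_IN_1 was 0.38 (SE 0.053) and 0.18 without 4, CD14 with EM127 0.31 (SE 0.061) and 0.04 without 2, and CD70 with the antimetabolite 6_Thioguanine 0.31 (SE 0.053) and 0.09 without 3. The PLK inhibitor BI_2536 gave 0.23 (SE 0.038) for TNFRSF1B and 0.02 without replicate 1, UNC0321 0.19 (SE 0.044) for CSF1R and 0.04 without 1, and HJ_PI01 0.17 (SE 0.040) for CD47 and 0.07 without 1. CBP/p300_IN_3 gave −0.13 (SE 0.032) for CD47 and −0.07 without replicate 4. Smaller calls lost without 1 library were HLA_ABC with Dot1L_IN_5 (0.09; 0.07 without 4, 0.09 without 1, 2 or 3), IgG with UNC1215 (−0.15; −0.13 without 3, −0.12 without 4) and CD123 with EZM0414_(TFA) (−0.10; −0.07 without 3, −0.09 without 2, −0.10 without 1). Fas with AZ505 (−0.15; −0.13 to −0.16 without each) and the largest fall of Flt3 (−0.14; −0.09 without 3) were lost too. In all, 16 of the 29 named pairs of Assay 2 lost the call without some library and 13 kept it without each.

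Plates 1, 2 and 3 share a column order, and wells at the same place resembled each other although they held different compounds. Well totals correlated between plates across 320 places with Spearman's rho of 0.706 to 0.811, and AnnexinV levels with 0.444 to 0.612. The other antibodies correlated less at the median. CD47 (0.366 to 0.465), CD33 (0.382 to 0.539) and CD11b (0.378 to 0.467) came close to AnnexinV. Among the lowest were IgG at 0.0485 to 0.174 and CD123 at 0.0558 to 0.140. Place 281 held FHD_286 on plate 1, Dot1L_IN_4 on plate 2 and GSK620 on plate 3; AnnexinV was 0.32, 0.35 and 0.38 there, CD11b −0.36, −0.40 and −0.49 and Fas 0.36, 0.44 and 0.26. When each compound of these plates was set against its own column place on the other plates, 59 of 16320 pairs changed, 28 up and 31 down, in place of 264 (194 up and 70 down), and 22 pairs of 14 compounds were in both lists. Besides SGI_1027, these included the oxygenase inhibitor IOX1 with CD33 (0.32, SE 0.056; 0.27, SE 0.063, at its place), Gandotinib with CD11b (−0.22; −0.24 at its place), Aurintricarboxylic_acid with CD86 (−0.20; −0.18) and the HDAC inhibitor Tucidinostat with IgG (0.16; 0.19). Of these, IOX1 and Tucidinostat kept the call without each library.

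**Figure D3:**
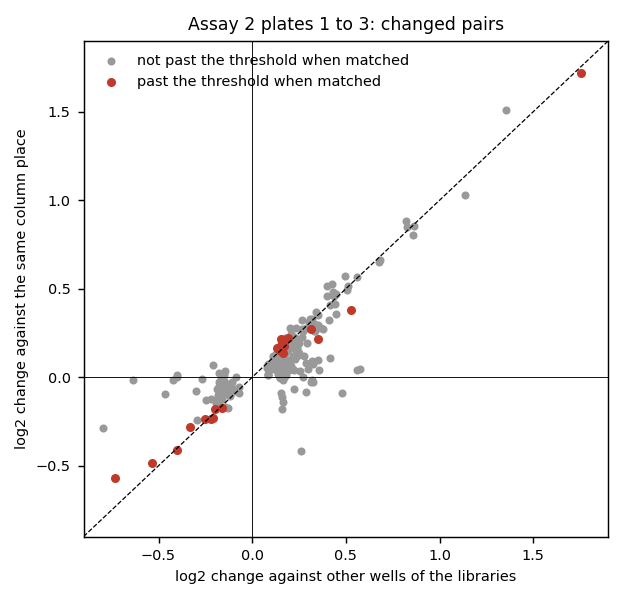
Log2 change of the 264 changed pairs of plates 1, 2 and 3 of Assay 2 against the other wells of the libraries (horizontal axis) and against wells at the same column place on other plates (vertical axis); 1 point is 1 pair. The 22 pairs past the threshold on both axes are in red, and the largest is HLA_E with NV03 at 1.75 and 1.72, a value from 1 library.

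Well totals in Assay 2 changed for 15 of 1101 compounds, 10 up and 5 down, by the exact permutation test (two-sided). UNC4976_(TFA) lowered the total (−5.76 on the log2 scale, n = 4 libraries, exact adjusted p = 1.6e-07), as did Pep2m,_myristoylated_(TFA) (−5.59) and PROTAC_BET_degrader_2 (−5.09), and all 3 lay at column place 172 of their plates. R_59_022_(hydrochloride) was at −2.95, with libraries from −7.01 to 0.88, and lost the call without replicate 3 (−1.85) or 4 (−1.60). Cerdulatinib_(hydrochloride) was at −1.42. The highest totals were those of Pseudoprotodioscin (1.88), MAT2A_inhibitor_1 (1.86) and Chiauranib (1.84). Without replicate 1 or 2 the count fell to 4 compounds, with 0 rises, and Cerdulatinib_(hydrochloride) and MAT2A_inhibitor_1 were lost; Chiauranib was lost without 1, 2 or 3 and Pseudoprotodioscin without each. limma called 60 and setting all compounds against other compound wells 8.

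The first-round and second-round libraries of Assay 2 differed in 94 of 18700 pairs by the interaction term in edgeR, 39 higher in the second and 55 higher in the first, a balance that turned to 68 and 52 with total-count scaling and was 47 and 51 with DESeq2 size factors. The largest differences were HLA_E with NV03 (−2.41, second minus first, SE 0.12), CD86 with the HDAC inhibitor Trichostatin_A (−2.31, SE 0.17), CD11b with Oxamflatin (−1.91, SE 0.13), CD33 with SIRT2_IN_11 (1.47, SE 0.25) and CSF1R with NCDM_32B (1.43, SE 0.12). In 71 of the 94 pairs (75.5%), a single well lay at least 3 times as far from the reference as any of the others, as 3.40 for NV03 and 2.93 for Trichostatin_A. Splitting the same libraries into odd and even numbers gave 72 pairs.

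Azacitidine and PFI90 were tested in both assays, where Assay 2 names them 5_Azacytidine and PFI_90. AnnexinV rose by 0.12 (SE 0.019) with azacitidine in Assay 1 and fell in Assay 2 (−0.16, SE 0.046), a difference of 0.28 (SE 0.050, adjusted p = 4.9e-07). The reference was control wells in Assay 1 and all other compound wells of the plate in Assay 2. In Assay 1 the rise of AnnexinV was smaller than that of CD45. Against wells at its column place the Assay 2 value was −0.06 (SE 0.056), not past the threshold. CD33 differed by 0.12 (SE 0.049) and CLL1 by −0.17 (SE 0.054). PFI90 differed in CSF1R (0.18, SE 0.066), CD86 (0.16, SE 0.059), HLA_E (−0.11, SE 0.044) and IgG (−0.10, SE 0.040). Its Assay 1 values come from 7 wells of 1 library, and none of its calls there stayed past the threshold when matched by column place. Over the 14 shared antibodies the profiles of the assays correlated with r = −0.166 (Spearman's rho −0.0374) for azacitidine and −0.294 (rho −0.424) for PFI90. Differences were tested by the normal distribution from the edgeR standard errors, adjusted over 28 values, and 7 passed. Only 2 passed without replicate 1, 4 without 2, and 1 without 3 or 4, and doses in either assay are not given in the sources used here.

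HDAC inhibitors were the class with a shared shift: IgG was 0.05 at the median of 20 inhibitors and −0.01 at that of 1081 other compounds, and 16 of the 20 lay above the latter (exact Wilcoxon rank-sum test, two-sided, p = 3.2e-05, adjusted p = 0.00758). The list of members was fixed beforehand and left further HDAC inhibitors, such as LMK_235, among the other compounds. With edgeR, 7 members rose: Resminostat_(hydrochloride) by 0.20 (SE 0.028), Tucidinostat by 0.16 (SE 0.036), Vorinostat by 0.16 (SE 0.041), Mocetinostat by 0.15 (SE 0.040), Panobinostat by 0.14 (SE 0.027), Fimepinostat by 0.14 (SE 0.031) and Ricolinostat by 0.12 (SE 0.027). Resminostat_(hydrochloride), Panobinostat, Fimepinostat and Ricolinostat are the only members on plate 4. On that plate IgG was positive for 92 of 141 compounds against shared control wells, in the separate fit used for random names. The class was not tested against all other compound wells there. Against wells at the same column place, Vorinostat was at 0.06 (adjusted p = 0.676) and lost the call, while Tucidinostat (0.19) and Mocetinostat (0.21) kept it. IgG cannot be read with itself as the denominator, and with total-count scaling the median was 0.06. Vorinostat was lost without replicate 1 (0.14) or 4 (0.13), Mocetinostat without 1 (0.15) or 3 (0.14), Fimepinostat without 2 (0.10) or 3 (0.13) and Ricolinostat without 3 (0.11) or 4 (0.09). The next lowest adjusted p values, neither past the threshold, belonged to CD11b with HDAC inhibitors (−0.07, 4 of 20 above the median of the others, adjusted p = 0.0763) and CD123 with BET bromodomain inhibitors (0.02, 14 members, adjusted p = 0.0954). DNMT inhibitors (5 members, CD11b 0.09, adjusted p = 0.352) and LSD1 inhibitors (9 members, TNFRSF1B −0.03, adjusted p = 0.511) did not pass, and of 238 tests 24 were under an unadjusted p of 0.05. The fixed list of DNMT inhibitors did not hold SGI_1027, which stood among the other compounds. The adjusted p for HDAC inhibitors and IgG was 0.0557 without replicate 3 and 0.0544 without replicate 4, where the medians differed by 0.07 and 0.06 as against 0.06 with all replicates. It was 0.182 on plates 1, 2 and 3 alone (16 members), which is past no threshold used here.

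**Figure D4:**
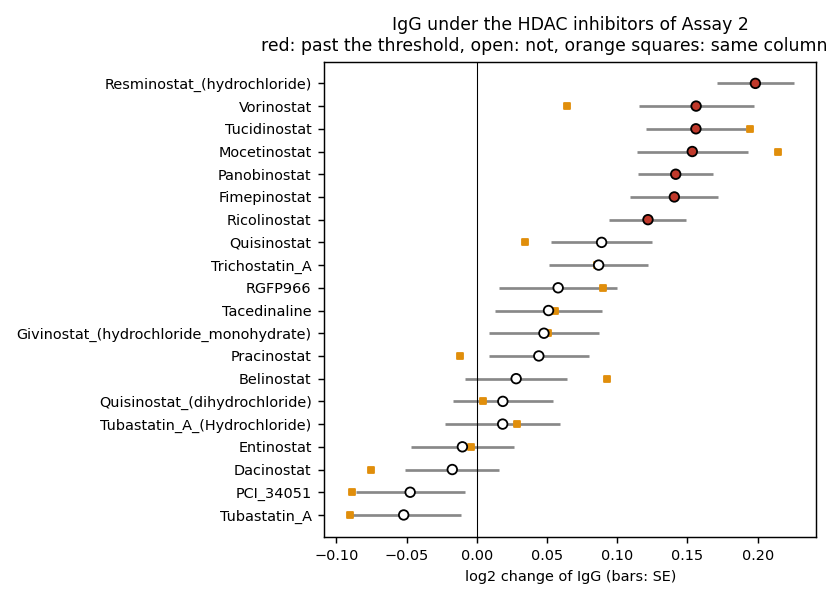
Log2 change of IgG for each of 20 HDAC inhibitors in Assay 2 (error bars SE; red past the threshold, open not) and, for those on plates 1, 2 and 3, against wells at the same column place (orange squares). The 7 members past the threshold lie between 0.12 and 0.20.

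Of 108 pairs of structurally related compounds, 20 differed in at least 1 antigen, with 31 of 1836 differences past the threshold and a median 95% half-width of 0.13. Doses are not given in the sources used here, so no pair is known to be matched in dose. The BET inhibitor (+)_JQ_1 and its inactive enantiomer (R)_(_)_JQ1_Enantiomer differed in 0 of 17 antigens by the normal test on edgeR standard errors. The largest difference was −0.19 for CD38 (95% interval −0.32 to −0.07, adjusted p = 0.116). Tofacitinib and its stereoisomer (3R,4S)_Tofacitinib differed in 0 of 17, with 0.12 for CD33 (−0.03 to 0.26), and Ruxolitinib and Ruxolitinib_(S_enantiomer) in 0 of 17, with −0.05 for CLL1 (−0.18 to 0.08). Ritlecitinib lay above (2R,5S)_Ritlecitinib in CD47 by 0.23 (0.13 to 0.34; 0.14 without its replicate 3), and PT2399 above (Rac)_PT2399 in HLA_E by 0.25 (0.13 to 0.37; 0.06 without its replicate 1). The bromodomain inhibitor GSK6853 lay above its control compound GSK9311 in CD86 by 0.43 (0.28 to 0.57; −0.04 without its replicate 4), and GSK484_(hydrochloride) above GSK106 in TNFRSF1B by 0.22 (0.10 to 0.34; 0.00 without its replicate 2). The nucleosides 5_Azacytidine and Decitabine, which differ by the hydroxyl group of the ribose, differed in CLL1 by 0.22 (0.10 to 0.35); the difference in CD14 was of like size (−0.23, −0.38 to −0.09) but missed the adjusted threshold (adjusted p = 0.0796). Prodrugs and parents differed in 0 of 51 antigen values (5 at an unadjusted p under 0.05).

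Salt and hydrate forms of one compound made up 80 of the related pairs, and 26 of their 1360 differences passed. Seclidemstat and Seclidemstat_(mesylate) differed in 6 antigens, as in Fas (0.23, 95% interval 0.15 to 0.32) and CSF1R (−0.30, −0.42 to −0.17). Cerdulatinib and Cerdulatinib_(hydrochloride) differed in 4, CD11b (0.47, 0.30 to 0.63), AnnexinV (−0.37, −0.50 to −0.24), Fas (−0.34, −0.43 to −0.25) and HLA_ABC (0.22, 0.14 to 0.30). In both pairs the forms lay on different plates, 1 with control wells and 1 without. ENMD_2076 exceeded ENMD_2076_(Tartrate) in CD47 by 0.36 (0.27 to 0.46; 0.04 without its replicate 1), and Ilginatinib_(maleate) exceeded Ilginatinib_hydrochloride in CD70 by 0.72 (0.38 to 1.06), where its own change of 0.73 was 0.03 without replicate 4. Of the 31 differences, 16 moved by more than 1.5 times when 1 library of either compound was left out.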

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

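Chosen only after the results were seen were the tests of column place, of single wells and of odd against even libraries, the leave-one-out counts of the comparison of both assays and the SpikeIn ratio.

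In 10 of 52 groups of 4 or 5 libraries tested, 1 library stood far from the rest, where chance gives about 1 in 20. Its log2 change was 0.61 for DECAMETHONIUM_BROMIDE with CD86 (the others 0.05 to 0.11) and 0.75 for ARIPIPRAZOLE with CD14 (0.06 to 0.19) in Assay 1. In Assay 2 it was 3.40 for NV03 with HLA_E (0.01 to 0.20), 1.71 for T_3775440_hydrochloride with CD86 (0.03 to 0.13), 1.04 for Simmiparib with CD11b (0.06 to 0.17) and 0.87 for EM127 with CD14 (0.01 to 0.07). It was 0.75 for 6_Thioguanine with CD70 (0.06 to 0.17), 0.68 for BI_2536 with TNFRSF1B (0.01 to 0.05), 0.55 for UNC0321 with CSF1R (0.01 to 0.07) and 0.44 for HJ_PI01 with CD47 (0.04 to 0.09). All 10 named pairs were chosen as the largest rises that went the same way in every library, a rule that favours such wells.

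The first-round and second-round libraries of Assay 2 differed in 94 pairs by edgeR's interaction term. Among the named pairs, the second minus the first round was 0.46 for KDM4D_IN_1 with CD33, −2.41 for NV03 with HLA_E, 1.09 for T_3775440_hydrochloride with CD86, −0.55 for Simmiparib with CD11b, −0.48 for EM127 with CD14 and −0.37 for BI_2536 with TNFRSF1B. Between the assays, 5_Azacytidine differed in CD33 (0.12), AnnexinV (0.28) and CLL1 (−0.17), and PFI_90 in HLA_E (−0.11), IgG (−0.10), CSF1R (0.18) and CD86 (0.16), each as Assay 1 minus Assay 2 and adjusted over 28 tests. The ratio of SpikeIn to antibody counts, which enters no planned comparison here, was higher with AZACITIDINE than in control wells of Assay 1 (0.76 on the log2 scale, 0.22 to 1.26 over 5 libraries, exact permutation p = 0.000526, adjusted p = 0.0437 over 83 compounds). It did not pass without replicate 1 (0.79), 2 (0.63), 3 (0.77) or 5 (0.70), and did without 4 (0.89).

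The 264 changed pairs of plates 1, 2 and 3 in Assay 2 were set against 3 technical explanations. Leaving out wells with totals under 25% of the median ended 8 of the 264 calls, so such wells did not account for most of them. Only 21 of the 4460 wells of Assay 2 lay under that bound, so few calls could be lost this way. The count thus says nothing of totals above that bound, which were not tested apart from place. Well place may account for most of them: of 195 pairs that went one way in all libraries, 22 stayed past the threshold against wells at the same column place, where the median size went from 0.17 (SE 0.044) to 0.088 (SE 0.053) and 176 kept their sign. The wider error of the matched comparison ended part of these calls, since 121 would have passed with their former size. The wells at the same place held other treated compounds, so like effects of those compounds could end a call too. The comparison cannot tell this from an effect of place. Single aberrant wells stay open for 79 of the 264, in which libraries went both ways or the median lay far below the fitted change; no biological explanation of the 22 was tested.

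The 11 calls of PFI90, IFNG and TNFa in Assay 1 form another group: CSF1R rose with all 3 and CD45 fell with IFNG and TNFa, and the rest were CD47 and CD70 with TNFa, AnnexinV with IFNG, and CD11b, CD86 and HLA_E with PFI90. Well place may account for them: against control wells at the same column place edgeR kept 0 of 11, with 2 of 45 matched values under an unadjusted p of 0.05. Control wells at those places differed from other control wells in the direction of all 11 calls, and past the threshold for 10 of them. The median change went from 0.10 (SE 0.025) to 0.037 (SE 0.041), and 3 of the 11 would have passed with their former size. With 1 library per treatment, an effect of the treatments of the size left over cannot be excluded.

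The higher IgG signal with HDAC inhibitors is the last pattern weighed. Low well totals are argued against as the sole cause for the class as a whole: the members' median total differed from that of other compounds by −0.105 on the log2 scale (20 members, exact rank-sum p = 0.394), inside the bound written before the test. The 7 members called lay between 63.8% (Fimepinostat) and 105% (Panobinostat) of the reference. Trichostatin_A, Quisinostat_(dihydrochloride), Pracinostat and Dacinostat, at 139% to 264%, were not called (−0.02 to 0.09). Tacedinaline, at 61.2%, was not called either (0.05). An effect of the total among members was not tested and is not excluded. The control wells of plate 4 are argued against as the sole cause, since the 16 members on plates 1, 2 and 3, where no such wells were used, lay 0.055 (0.0551) above the other compounds (unadjusted p = 0.00164). Matched by column place, they lay 0.046 above them (exact rank-sum p = 0.0368, adjusted p = 0.584). In that setting 17 of 238 tests were under an unadjusted p of 0.05, and the criterion was written after the data were seen. This test therefore cannot exclude place as a cause. Neither this value nor that for plates 1, 2 and 3 passed the adjustment over 238 tests with 16 members. AnnexinV lay higher with the members too, at a median of 0.029 against 0.00069 (15 of 20 above, exact rank-sum p = 0.0198, adjusted p = 0.352). At an unadjusted p under 0.05, CD70, Flt3, HLA_E and TNFRSF1B were also higher and CD11b and CLL1 lower, none past the adjustment. A shared effect of the inhibitors on unspecific antibody binding or on cell surface remains an untested hypothesis, and IgG on dying cells was not measured apart.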

How the results depend on the processing

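Chosen only after the results were seen were the counts matched by column place, those on plates 1 to 3 alone, the SpikeIn denominator, the restriction to pairs that went one way, the odd and even libraries, and the leave-one-out counts for classes and for both assays; the other settings were planned.

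The 116 changed pairs of Assay 1 became 57 with no replicate block, 72 against all other compound wells, 2 at a fold change of 1.5, 13 with SpikeIn as the denominator (1 up, 12 down) and 44 to 113 without each replicate; total-count scaling, DESeq2 size factors, DESeq2's Wald test (115) and limma-voom (98) kept the count within 1.5 times. IgG as the denominator (114, of which 55 were among the 116), CD45 (112, of which 43) and a single fit of every well (174, of which 91) changed more of the pairs than of the count. The fold threshold and the smaller samples lower counts by construction; for the others the cause was not tested. The 11 pairs of PFI90, IFNG and TNFa became 0 when matched by place. The 0 changed well totals of the permutation test became 1 with limma, 15 against all other compound wells, 0 to 7 without each replicate and 0 without the block.

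The 391 changed pairs of Assay 2 became 594 with IgG as the denominator, 76 with no replicate block and 14 at a fold change of 1.5; the leave-one-out counts were 263 to 289. On plates 1, 2 and 3, 264 became 59 when matched by place. The 15 changed totals became 60 with limma, 8 against other compound wells and 4 to 10 without each replicate. The 7 differences between assays became 1 to 4 without each replicate number. The 1 class became 2 with total-count scaling, 0 when matched by place (17 of 238 rank-sum tests under an unadjusted p of 0.05), 0 on plates 1 to 3 alone (23 under it) and 0 to 2 without each replicate. The 31 differences between related compounds became 4 with no replicate block. Apart from the fold threshold and the smaller samples, the cause was not tested.

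Of 350 values of the 21 named pairs of Assay 1 under alternatives, 284 kept direction and call, 51 kept direction only and 15 reversed. With CD45 as the denominator these were VINPOCETINE with HLA_ABC (0.057), AZACITIDINE with CD33 (−0.045) and CD38 (−0.045), CLAVULANATE_LITHIUM with HLA_E (−0.061), PFI90 with HLA_E (0.032) and ARIPIPRAZOLE with CD38 (0.029). With SpikeIn they were RABEPRAZOLE_SODIUM with CD47 (−0.031), AZACITIDINE with CD45 (−0.58), CD33 (−0.62) and CD38 (−0.63), CLAVULANATE_LITHIUM with HLA_E (−0.42) and AnnexinV (−0.34), SODIUM_PHENYLBUTYRATE with CD70 (0.017), DROSPIRENONE with IgG (−0.19) and EUCALYPTOL with IgG (0.038). Of 402 values of the 29 pairs of Assay 2, 323 kept both, 77 direction only, and SGI_1027 with CD123 (−0.21) and Flt3 (−0.19) reversed with IgG as the denominator; the cause was not tested. A fit of every Assay 2 well at once and classes from a target list were not run, and a minimum mean count of 10 per antibody removed none, so it tests nothing. SpikeIn counts, 9250 to 22419 per library in Assay 1 and 29 to 1832 in Assay 2, were too few in Assay 2 for a denominator. Changes of 1.1-fold lay at the limit of what these depths and spreads detect.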

Other observations

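Chosen only after the results were seen was the test of salt forms; the random assignments of names were planned.

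Among compound classes that did not pass the adjusted rank-sum test, the 6 inhibitors of Aurora kinases, PLK or KSP had a median CD11b change of −0.09, with 0 of 6 above the median of other compounds (adjusted p = 0.124, exact Wilcoxon rank-sum test, two-sided). The 4 activators of protein kinase C, whose best-known members drive myeloid lines toward macrophages, had CLL1 at 0.07, above the other compounds' median in 4 of 4 (exact adjusted p = 0.219). The 4 topoisomerase inhibitors had CD86 at 0.13, above it in 4 of 4 (exact adjusted p = 0.408), and the 6 menin inhibitors had AnnexinV at 0.03 (exact adjusted p = 0.823). Each is the antibody with the lowest p for its class. The topoisomerase inhibitor Camptothecin had CD86 at 0.68, with libraries that went both ways. Ingenol_Mebutate, a protein kinase C activator, had CLL1 at 0.18, and at 0.01 against wells at its column place.

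Single wells that rose by at least 1 on the log2 scale while the other libraries of the pair stayed under 0.3 numbered 34, against 8 that fell so, among 18717 pairs of Assay 2.

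Random assignments of compound names to wells within each library gave fewer changed pairs than the real one. In Assay 1 the real assignment gave 116 changed pairs and the highest of the others 16, so that 1 of 100 assignments, the real one, gave as many. In Assay 2 a fit with 1 dispersion per plate and antibody gave 370 against 73 to 99 in the others (1 of 25), and the related compounds gave 31 against at most 16 (1 of 25). Chance alone can therefore be excluded for the counts as a whole. It cannot for single pairs of Assay 2, since random names also gave 73 or more changed pairs. A random assignment also breaks the link between a compound and its column place, so place cannot be excluded either.

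If the active part of a compound set its profile, its salt or hydrate forms should resemble each other over the antibodies. The mean correlation of 80 such pairs was 0.0193, inside the range of −0.064 to 0.079 that random pairings gave (1-sided permutation p = 0.357), and with wells matched by place it was 0.000235 over 54 pairs. This negative result gives no sign of a shared profile, and may reflect that most compounds moved antigens by less than the spread between wells.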
